A study of Mus musculus with 8 samples.

How the data were processed

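The data are RNA sequencing counts from mouse immune cells of spleen and lymph node, taken before disease signs and cultured for 4 days with anti-CD3 and IL-23, TGF-β, IL-6 and IL-12. Per the labels, 8 libraries fall into 4 groups of 2, by strain (TCR1640 or SJL/J) and sex, and groups and replicate numbers were taken from the sample titles. The labels' protocols name a KAPA kit for stranded mRNA libraries made from 500 ng of RNA. The authors deposited whole-number counts per Ensembl gene, not normalized, and the submitters' processing notes name bcl2fastq 2.17, Bowtie2, HTSeq and the mm10 build. The strand setting of the counting and the annotation release are not given in the sources used here. Nothing in the labels says whether the 2 libraries of a group came from separate mice.

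The table holds 52636 genes and no summary rows. Symbols, positions and strands came from GENCODE mouse release M21 on GRCm38, the assembly that mm10 names, and 147 identifiers were not in it. Column totals ran from 3765291 to 5116467 counts.

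The fit planned before the data were examined used edgeR 4.0.16 under R 4.3.3 on all 8 columns. It had group means, TMM normalization, filterByExpr, the quasi-likelihood F test, and a two-sided Benjamini-Hochberg adjusted p threshold of 0.05. The other settings fixed at that time were RLE and upper-quartile factors, no filter, a filter of 1 CPM in 4 libraries, DESeq2 1.42.0, limma-voom (limma 3.58.1), the replicate number as a block, fits of the 2 groups compared, fits without receptor segments or sex-linked lists, and leaving out each library. Gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, where at least 5 members were tested.

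Columns were compared with a chi-square test over genes with at least 20 counts, leaving out Gm43333. Within each group the 2 columns gave a chi-square per degree of freedom between 1.05 and 1.08, against 3.12 to 17.05 between groups. The values within pairs lay slightly above 1, so the columns differed by a little more than sampling noise. The 2 columns of a group were therefore summed and counted as 1 sample, a choice made after seeing the data. Gm43333 differed between the numbers in every group, with 14137 and 4769 counts in the female columns labelled TCR1640. It was left out of this check only.

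With 1 sample per group, comparisons of 2 groups have no replicate check and carry no p-values here. They are given as log2 ratios of summed counts on TMM-scaled library sizes, with exact 95% intervals that cover counting error only. A ratio against 0 counts was computed against a floor of 3 counts over the group. In list medians, members at 0 counts in a group stood at that bound. Lists are described by the percentile of their median among 10000 random lists matched on mean expression. The random lists draw genes independently, so the percentiles allow neither for genes that move together nor for spread between mice. A gene was counted as apart when it differed by at least 2-fold, its interval excluded equality, and its mean log2 CPM was at least 3. This rule was chosen after seeing the data, and its expression floor was added after a first version without it counted 137 to 155 genes between the 2 columns of a group. The numbers of genes called by the planned fit are given too, and they compare libraries, not conditions. For the averages over sex or strain, an additive edgeR model was fitted to the 4 summed samples (2 against 2, 1 residual degree of freedom), also chosen after seeing the data. Its residual is the part of each sex difference that differed between strains, so its SE and p-values do not measure spread between mice. They use a spread estimated with information shared across genes (common coefficient of variation 9.78%), not a gene's own residual alone. Each SE is the log2 change over the square root of F.

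Features on the strand opposite to known genes held many of the counts. Pairs of a coding gene and an overlapping noncoding feature were kept with at least 200 counts each and 100 bp of overlap. Over 716 such pairs, the noncoding feature had the higher count in 76.7% (exact 95% interval 73.4 to 79.7). Between 68.1% and 69.9% of each group's counts lay in features that share exon sequence with a gene on the other strand or have no position. A subset of 279 pairs was chosen for a well-counted coding gene and a noncoding count well above it. There, log2 ratios of the coding gene and of the feature opposite to it correlated across genes. For strain labels r was 0.89 (rho = 0.86) in females and 0.84 (rho = 0.78) in males. For sex it was 0.55 (rho = 0.56) in TCR1640 and 0.42 (rho = 0.42) in SJL/J. Genes are not independent replicates. Ratios are therefore described mainly for genes without exon overlap on the opposite strand, and an overlapping gene is named with its partner and is uncertain. If the strand setting was reversed, the counts of genes without overlap would come only from reads off their expected strand. Their ratios would then be uncertain too, which was not tested. Reads shared by paralogs cannot be told apart in such a table.

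Named genes followed a rule fixed in advance: the sex-linked genes; up to 8 genes per direction with the largest change among called genes with a mean log2 CPM of at least 3 and columns that do not overlap between sides; up to 4 members of each list that passed camera; 11 T helper and lineage genes; and up to 3 receptor segments per direction. Predicted, clone-named, sex-linked and segment genes were left out of the second part. The restriction to non-overlapped genes was added after seeing the data, and some members are left out for length. Outside this rule, Gm43333, Ly6g, Ahr, Aldoc, Ccne1, Mzb1, Prdm1, Ccr1, Ccr2, Cxcr4, Cx3cr1 and Cd163l1 are named, chosen after their values were seen. Il21 and Il6ra met the rule in some comparisons only, and were also named after their values were seen. The result of 1 gene is not reported here.

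The fits were tested on simulated counts with 200 changed genes. The changed genes were drawn only from the more highly counted of the tested genes, and all genes of a fit were given the same spread. Recovery among the genes with the fewest counts was therefore not measured. For male against female in TCR1640 on 8 columns, 96.5% of 2-fold changes were recovered with 8 false calls among 15484 genes. For the additive sex comparison 96.5% were recovered with 10 false calls among 17136 genes, and for the additive strain comparison 98.5% with 8 among 17151. These simulations assume that the model's spread is the true spread, which 1 sample per group cannot test.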

Results

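Immune cells from spleens and lymph nodes of mice aged 35 to 55 days were stimulated in culture toward a mixed TH1/TH17 state, and polyadenylated RNA was counted per gene. TCR1640 mice carry a transgenic T cell receptor against a myelin protein on the SJL/J background and develop spontaneous autoimmune encephalomyelitis. SJL/J mice were the strain control. The design compares males with females within each strain, and the strains within each sex. The summed counts were 7937262 for TCR1640 females, 10005975 for TCR1640 males, 8378659 for SJL/J females and 7678860 for SJL/J males. The 2 columns of each group differed by little more than sampling noise and were counted as 1 sample, so n = 1 per group throughout.

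The sex labels were checked first. Counts for Eif2s3y (ENSMUSG00000069049, chromosome Y, 1010543 to 1028847 on GRCm38) were 105 and 124 in the columns labelled TCR1640 male and 87 and 93 in those labelled SJL/J male, and 0 in all 4 female columns. Ddx3y had 64 to 96 counts in male columns and at most 1 in female columns, and Kdm5d had 49 to 83 against at most 3. Uty had 24 to 36 counts in male columns and at most 1 in female columns. Xist, the RNA that silences an X chromosome, had 668 to 784 counts in female columns and 25 to 44 in male columns. The Tsix feature, on its opposite strand, had 3553 to 3935 against at most 1. Since the strand setting is in doubt, these may be reads of Xist. The sex labels matched these genes in all 8 columns.

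T cell receptor segments, which a receptor transgene would narrow, went against the strain labels. In the libraries labelled SJL/J, Traj43 took 75.6% of alpha joining segment counts in females (exact 95% interval 71.3 to 79.4) and 79.2% in males (75.05 to 82.95). In the libraries labelled TCR1640 it took 5.04% (1.87 to 10.7) and 2.91% (0.951 to 6.65). The Trav12 family took 53.2% and 54.7% of alpha variable counts in females and males labelled SJL/J, and 5.98% and 5.96% in those labelled TCR1640. Trbv2 took 58.3% and 63.1% of beta variable counts in those labelled SJL/J, against 19.7% and 20.6%. The effective number of beta variable segments, the inverse of the summed squared shares, was 2.75 and 2.37 in the libraries labelled SJL/J and 7.80 and 7.42 in those labelled TCR1640. Strain names below are therefore the labels of the libraries, and every strain direction is drawn between labels that these segments go against.

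**Figure D1:**
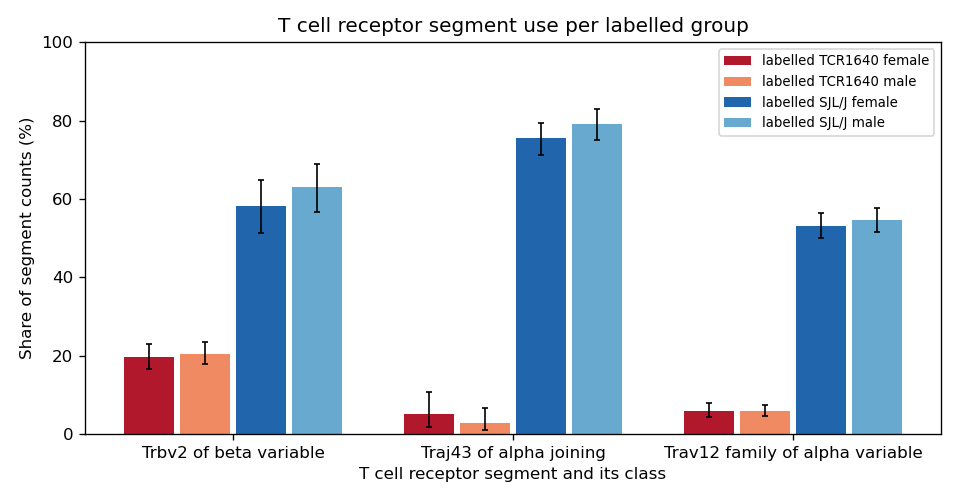
Share of T cell receptor segment counts (%) taken by Trbv2, Traj43 and the Trav12 family, each within its segment class, in the 4 labelled groups. Bars are shares of summed counts and lines are exact 95% binomial intervals for counting error. Traj43 takes 75.6% and 79.2% in the groups labelled SJL/J and 5.04% and 2.91% in those labelled TCR1640.

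In females, genes of naive and CD8 T cells were higher in the library labelled TCR1640, and genes of platelets, mast cells and neutrophils were lower. Tcf7, a transcription factor of naive T cells, had a log2 ratio of 1.79 (counting interval 1.69 to 1.89). Cd8a (ENSMUSG00000053977, chromosome 6, 71373427 to 71379173 on GRCm38) stood at 2.76 (2.53 to 2.98) and Cd8b1 at 2.54 (2.30 to 2.78). Ccr7 stood at 1.47, Klf2 at 2.18, Igfbp4 at 2.25, Ggt1 at 2.65 and Scml4 at 2.37. Pf4, a platelet chemokine, had 4 counts against 436, a log2 ratio of -6.67 (-8.55 to -5.30). Csf2rb and Csf2rb2, receptor chains for GM-CSF and related cytokines, stood at -3.83 and -3.87, Ifitm3 at -3.37, Gata2 at -3.36, Rab44 at -3.59, Serpina3g at -3.04 and Itga2b at -2.92.

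Among the fixed lists in females, the 11 non-overlapped naive and memory T cell genes had a median log2 ratio of 1.04, above all 10000 matched random lists, and the 14 CD8 and cytotoxic genes 1.17, also above all. The 10 mast cell and basophil genes had a median of -3.44 and the 12 erythroid and platelet genes -2.72, each below all random lists, and the 10 neutrophil genes -2.12 (percentile 0.01). The 10 Th17 genes had a median of -1.02, below all random lists, and all 19 with overlapped members -0.52. Il17a stood at -1.29 (-1.44 to -1.14), Il17f at -1.12 and Il22 at -1.33. The 16 genes of G2 and mitosis had a median of -0.66, with Mki67 at -0.71. The 15 interferon gamma response genes had a median of 0.47 (percentile 99.95) and the 14 B cell genes 0.64 (99.91), or 0.35 (98.54) over all 18. Il10 stood at 1.30, Cd4 at -0.55 and Ifng at 0.27 (-0.14 to 0.69). In all, 153 non-overlapped genes were higher and 104 lower by the rule of size, of 5858. Without its expression floor 530 were higher and 575 lower, of 11181, so this balance turns with the floor. With the floor, the rule counted 6 to 8 genes between the 2 columns of a group. The planned fit called 5690 of 15793 genes between these libraries, 2947 higher and 2743 lower, and DESeq2 called 3077. With upper-quartile factors 2733 were higher and 2938 lower, so the balance of directions is not settled.

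In males, genes of naive and CD8 T cells were again higher in the library labelled TCR1640, and genes of platelets, mast cells and neutrophils lower. Cd8a had a log2 ratio of 2.63 (2.42 to 2.84) in the library labelled TCR1640 over that labelled SJL/J, Cd8b1 2.25 and Tcf7 2.18 (2.08 to 2.29). Qrich2 stood at 3.00 and Ggt1 at 2.56. S100a9, a neutrophil alarmin, had 3 counts against 528, a ratio of -7.80 (-10.08 to -6.24). S100a8 had 0 against 171, 72.1-fold lower when set at the floor of 3 counts, and Ppbp 0 against 300, 127-fold lower at that floor. Ifitm3 stood at -4.29, Csf2rb2 at -4.02, Csf2rb at -3.80, Itga2b at -3.63, Serpina3g at -3.17, Gata2 at -2.93 and Rab44 at -2.87.

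The male list medians were 1.39 for naive and memory genes (above all random lists), 0.58 for CD8 and cytotoxic genes (percentile 99.98), -4.46 for neutrophil genes, -3.96 for mast cell and basophil genes, -2.04 for erythroid and platelet genes and -1.15 for Th17 genes, the last 4 below all random lists. Over all 19 Th17 genes the male median was -0.54. Not every CD8 and cytotoxic gene was higher, since Srgn stood at -0.75 in the planned fit. The 16 G2 and mitosis genes had a median of -0.69 and the 11 glycolysis genes -0.56 (percentile 0.01). The 15 interferon gamma response genes had a male median of 0.10 (percentile 76.9) and the 14 B cell genes 0.34 (98.1). Il17a stood at -1.55, Il17f at -1.36, Il22 at -1.10, Il23r at -1.95, Ifng at -0.90 (-1.26 to -0.55) and Il10 at 1.08. By the rule of size 208 genes were higher and 138 lower, and without its expression floor 616 and 741, so this balance turns with the floor. The planned fit called 6755 genes between these libraries, 3363 higher and 3392 lower, and DESeq2 called 3968.

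**Figure D2:**
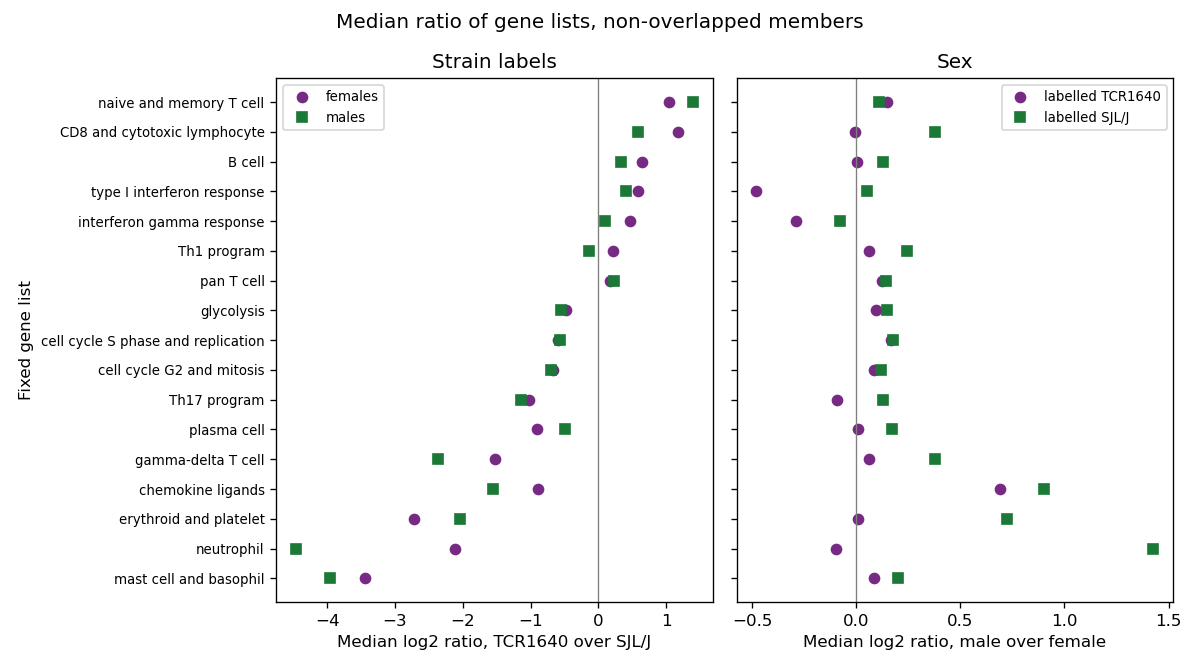
Median log2 ratio of 17 fixed gene lists over members without opposite-strand overlap, for strain labels in females and males (left) and for males over females in each labelled strain (right). Naive and memory T cell genes lie at 1.04 and 1.39 on the left, and neutrophil genes at -2.12 and -4.46. Each point is 1 sample against 1 sample.

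Over both sexes, the additive edgeR model of 4 samples called 4572 of 17261 genes between strain labels, 2305 higher and 2267 lower in TCR1640, and among the non-overlapped of these 1240 were higher and 1351 lower. The planned fit of 8 columns called 7821 of 15793, 3956 higher and 3865 lower. With upper-quartile factors it gave 3715 higher and 4102 lower, so the balance of directions is not settled. The gene values that follow come from the additive model. Their SE and adjusted p rest on its residual, with spread shared across genes, and not on spread between mice. Cd8a rose by 2.69 (SE 0.14, adjusted p = 5.57e-75), higher in 2 of 2 sexes. Gzmc, on the same CD8 and cytotoxic list, went the other way at -1.90. Csf2rb fell by 3.81 (SE 0.18, adjusted p = 5.55e-99) and Il17a fell by 1.42 (SE 0.13, adjusted p = 8.02e-26). Of 16 naive and memory T cell genes 13 rose and 3 did not pass (13 passed when adjusted over the list alone), with a camera adjusted p = 8.47e-16 in edgeR. Of 12 neutrophil genes 10 fell and 1, Ly6g, rose, of 10 mast cell and basophil genes 9 fell and 1, Kit, rose, and of 13 erythroid and platelet genes 9 fell. Of 22 G2 and mitosis genes 19 fell, among them Mki67 and Cenpf, and of 19 Th17 genes 11 fell and 3 rose, namely Il21, Ahr and Il6ra, which overlap Gm12534, Gm48236 and Gm42809 and are uncertain. Camera at the preset correlation passed 18 of 39 lists, and with an estimated correlation it passed 0, with adjusted p = 0.639 for the naive, neutrophil, mast cell, platelet, mitosis and Th17 lists. That test rests on 1 residual degree of freedom, which left it hardly able to pass any list. DESeq2 called 1410 genes in place of 4572, and the number 1 columns alone gave 2981. Tbx21, Foxp3 (overlapped by Ccdc22) and Ifng did not pass in edgeR (adjusted p = 0.106, 0.252 and 0.168).

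In the libraries labelled TCR1640, interferon response genes were lower in the male than in the female. The 15 type I interferon response genes had a median log2 ratio of -0.48 (percentile 0.12) and the 15 interferon gamma response genes -0.29 (percentile 0.01). Ifit1 stood at -2.58 (-3.80 to -1.52), Iigp1 at -0.91 (-1.22 to -0.60) and Gbp7 at -0.53. The 6 neutrophil genes that could be compared, some with few counts, had a median of -0.10 (percentile 33.6) and the 11 erythroid and platelet genes 0.01 (56.2). Spp1, the secreted protein osteopontin, stood at -1.66 (-1.84 to -1.48), Ubxn8 at -1.80 and Gpr141 at -1.30. Rab44 stood at 1.34 (0.41 to 2.36), Grik5 at 1.29, Thop1 at 1.17, Psat1 at 0.93 and the chemokine Ccl5 at 0.91 (0.51 to 1.32). Il17a (0.08), Ifng (-0.28), Tbx21 (0.07) and Cd4 (0.09) had intervals that include equality. By the rule of size 6 genes were higher and 23 lower in the male (131 and 264 without the expression floor), and 1 of the 6 is Gm43333, whose counts differ between the columns of each group. The planned fit called 2562 genes between these libraries, 1085 higher and 1477 lower, and DESeq2 921. With upper-quartile factors 1304 were higher and 1325 lower, and among calls on non-overlapped genes 643 and 659, so the balance of directions is not settled. Without TCR1640 female 1 it called 1696 genes and without TCR1640 female 2 it called 1630.

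In the libraries labelled SJL/J, genes of neutrophils, red cells and platelets, and cytotoxic genes were higher in the male. The 10 neutrophil genes had a median log2 ratio of 1.43, the 12 erythroid and platelet genes 0.72 and the 14 CD8 and cytotoxic genes 0.38, each above all random lists. S100a9 stood at 1.42 (1.19 to 1.66), Elane at 2.22 (1.47 to 3.05), Hba-a1 at 1.81 and Pf4 at 0.73. Prf1, the pore-forming protein of killer cells, stood at 0.90 (0.72 to 1.09), Ifng at 0.90 (0.53 to 1.28), Ccl3 at 0.94, Ccl4 at 0.90 and Il10 at 0.76. Il17a stood at 0.34 (0.23 to 0.44). Qrich2 (-1.75), Aqp7 (-1.30), Klrg2 (-1.28) and Col23a1 (-1.21) were lower in the male. By the rule of size 1 gene, Hba-a1, was higher and 16 were lower, and without its expression floor 142 and 197. The planned fit called 1782 genes between these libraries, 741 higher and 1041 lower, and DESeq2 579. Among its calls on non-overlapped genes 531 were higher and 359 lower, and a fit scaled on those genes alone gave 278 higher and 382 lower, so the balance of directions is not settled. It called 1174 without SJL/J female 1, 1170 without SJL/J female 2, 1109 without SJL/J male 1 and 1155 without SJL/J male 2.

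The sex difference was compared between the labelled strains. Spp1 differed by -2.14 on the log2 scale, Hba-a1 by -1.87, Ubxn8 by -1.60, Utp15 by -1.44, AA467197 by -1.30 and Ifng by -1.18, each with a lower male-to-female ratio in the libraries labelled TCR1640. Qrich2 (1.80), Grik5 (1.71), Col23a1 (1.32) and Ccl5 (1.16) had a higher one. The 14 CD8 and cytotoxic genes had a median difference of -0.43 (percentile 0.07) and the 15 interferon gamma response genes -0.26 (percentile 0.25). Genes of some other cell types moved the same way. The 6 neutrophil genes that could be compared, some with few counts, stood at -1.08 (percentile 0.03). The 11 erythroid and platelet genes stood at -0.60 (percentile 0.34). Other lists did not share this: the 9 dendritic cell genes stood at 0.12 (percentile 86.7) and the 5 stromal and endothelial genes at 0.35 (90.0). The 6 mast cell and basophil genes stood at -0.03 (59.2) and the 14 B cell genes at -0.16 (26.4). The planned fit called 1612 genes, 838 higher and 774 lower, a test between single samples, and DESeq2 called 610. Among its calls on non-overlapped genes 323 were higher and 365 lower, and a fit scaled on those genes alone gave 319 higher and 208 lower, so this balance too is not settled. Across 15779 genes the log2 sex differences correlated with r = 0.15 (bootstrap interval over genes 0.09 to 0.24) and rho = 0.12, and genes are not independent replicates. Calls of the planned fit were shared by both labelled strains for 139 genes higher in males, against 50.5 expected. For genes lower in males 293 were shared, against 96.4 expected. The expected counts do not match genes on expression.

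Over both strains, the additive model called 190 of 17261 genes between sexes, 24 higher and 166 lower in males, and among the non-overlapped of these 22 were higher and 89 lower. The planned fit of 8 columns called 2759 of 15793, 1093 higher and 1666 lower. Among its calls on non-overlapped genes 785 were higher and 672 lower. A fit scaled on those genes alone gave 548 higher and 721 lower, so the balance of directions is not settled. The gene values that follow come from the additive model. Prf1 rose by 0.68 (SE 0.14, edgeR adjusted p = 0.000513), Ccl4 by 0.79 (SE 0.18, adjusted p = 0.00381) and Il10 by 0.63 (SE 0.17, adjusted p = 0.0214), each higher in 2 of 2 labelled strains. S100a9 rose by 1.32 (SE 0.21, adjusted p = 7.85e-07), a value set by the libraries labelled SJL/J, since those labelled TCR1640 held 5 and 3 counts. Kdm6a, which escapes X inactivation, fell by 0.91 (SE 0.17, adjusted p = 8.56e-05) and Eif2s3x fell by 0.61. Mtfr1 fell by 0.75, Zc3h12b fell by 0.88 and Aqp7 fell by 1.10. Of 12 neutrophil genes 4, S100a8, S100a9, Elane and Cxcl2, rose and 8 did not pass (7 passed when adjusted over the list alone), and of 19 interferon gamma response genes none passed, with camera adjusted p = 3.57e-06 and 0.00614 in edgeR. With an estimated correlation, 0 of the 39 lists passed (adjusted p = 0.755 for both), in a test that 1 residual degree of freedom left hardly able to pass any. In the planned fit 0 of 12 neutrophil genes were called (camera adjusted p = 0.462 in edgeR), and 11 of 18 interferon gamma response genes were lower (adjusted p = 5.31e-05, and adjusted p = 0.129 with an estimated correlation). The neutrophil result of the additive model therefore depends on the fit and rests on the libraries labelled SJL/J, since S100a8 and Elane had 0 counts in those labelled TCR1640. The count fell to 7 with DESeq2 (4 higher and 3 lower), to 12 from the number 1 columns alone and to 112 from the number 2 columns alone.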

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

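The tests in this part on segments, strand, column pairs and the 9 lists of other cell types were chosen only after the results, or part of their members, had been seen.

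The planned fit called 1612 genes for a sex difference that differed between the labelled strains, by a test of the difference itself. Once each pair of columns counts as 1 sample, no spread between mice is left to set against it.

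The difference between strain labels is the pattern with the most genes. If the labels were right, segment use in the libraries labelled TCR1640 should be the narrower. The lowest effective number of beta variable segments labelled TCR1640 was instead 2.70 times the highest labelled SJL/J, which argues against the receptor transgene being in the libraries labelled TCR1640. Strain labels exchanged in both sexes are a candidate explanation, on the same measurement read the other way: the highest value labelled SJL/J was 0.371 of the lowest labelled TCR1640. A lower share of T cells raising every other cell type alike is argued against by the span of 4.04 between the lists' median log2 ratios, from -3.70 for mast cells and basophils to 0.34 for B cells. That span speaks only to an even rise. A lower share of T cells with uneven rises of other cell types was not tested and stays open. The 13 non-overlapped pan T cell genes had a median log2 ratio of 0.18 in females (percentile 90.7) and 0.23 in males (95.6). A biological strain difference stays open as untested, since its direction rests on the labels, and no library was regrouped.

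The columns of a group form the second pattern. The largest chi-square per degree of freedom within a pair was 1.08, near the 1 that sampling alone would give but above it in every pair, and Gm43333, left out of this test, differed between the columns of every group. Repeat reads of one library with a small difference between runs are a candidate explanation. Separate mice that vary as libraries of different groups do are argued against by the same 1.08. Mice more alike than any groups here stay open.

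The counts opposite to expressed genes form the third pattern. The noncoding feature had the higher count in 76.7% of pairs, as a strand-marking kit counted with the opposite strand setting would give, which may be the source. Counting without regard to strand would lose the shared reads and is argued against by the same 76.7%. No biological explanation was tested.

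Splits of the 8 libraries into 4 and 4, each fitted with 2 sides, numbered 35. For strain labels the real split called 5709 genes and the highest other 8, and 1 split reached the real count. For sex the real split called 8 and the highest other 5709, the strain split, and 2 splits reached it. The bound set beforehand was wrong for this design, because 32 of the splits part near-identical columns and called 0 genes. Only 3 splits keep the columns of a group together, too few for a share under 0.05.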

How the results depend on the processing

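The additive models, the restrictions to non-overlapped genes and to genes with none within 1 kb on the opposite strand, and the fits of columns of 1 number were chosen only after the results were seen. DESeq2 called 921 genes for sex in TCR1640, 579 in SJL/J, 610 for the difference between these, 3077 for strain labels in females, 3968 in males and 993 for sex over both strains. In the same order, non-overlapped genes gave 1169, 660, 527, 2999, 3654 and 1269 calls, and 4357 for strain labels over both sexes. Genes clear by 1 kb gave 693, 397, 331, 2066, 2465, 742 and 2944. Fewer genes were tested in these restrictions. Leaving out each library in turn gave 1630 to 2649 calls for sex in TCR1640 and 1109 to 1780 in SJL/J, with a lone column assumed to vary like the other groups. Camera passed 81 list tests on the 8 columns, 17 with an estimated correlation, and fry 154. The additive sex model called 190 genes, 108 with upper-quartile factors, 118 with no filter, 7 with DESeq2, 102 among non-overlapped genes, 88 among genes clear by 1 kb, 12 from the number 1 columns and 112 from the number 2 columns. The additive strain model called 4572, and 1410, 2610, 1896 and 2981 with DESeq2, non-overlapped genes, genes clear by 1 kb and the number 1 columns. Apart from the restrictions, the cause was not tested. Leaving a sample out of the additive model left no residual degrees of freedom, so no such test exists. Within each group, the log2 CPM of the number 2 column was subtracted from that of the number 1 column per gene. Between groups these differences correlated with r from -0.0252 to 0.0299, which gives no sign of pairing across genes. Even so, Gm43333 was higher in the number 1 column and the total count in the number 2 column of all 4 groups. With the replicate number as a block 2658, 1889, 1687, 5747, 6815, 2872 and 7855 genes were called in the order above. Over 212 pairs of a named gene and a comparison, 3674 alternatives gave 3609 values on the same side of the threshold. Of the rest, 45 no longer passed and 20 newly passed, and of genes that passed in either fit 0 changed sign. Sign changes of genes that passed in neither fit were not counted, and alternatives without an adjusted p were left out. Many of these genes were picked as the largest changes among calls of the planned fit, so this count says little about stability.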

Other observations

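The additive strain model used here, and the genes Aldoc, Ccne1, Mzb1, Prdm1, Ccr1, Ccr2, Cxcr4, Cx3cr1 and Cd163l1, were chosen only after the data were seen; all directions are between labels that receptor segment use goes against. The estimated correlations rest on 1 residual degree of freedom, so those values say little. Genes of gamma-delta T cells and of antibody-secreting cells fell in the libraries labelled TCR1640. Of 7 gamma-delta genes 5 fell and 2 did not pass, with camera adjusted p = 3.56e-06 in edgeR and adjusted p = 0.639 with an estimated correlation. 5830411N06Rik fell by 3.71 (SE 0.48) and Zbtb16, the transcription factor PLZF, fell by 3.00 (SE 0.58), and the others that fell were Cd163l1, Trdc, which overlaps Trdv5, and Il17a, also on the Th17 list. Of 12 plasma cell genes 8 fell and 4 did not pass, with camera adjusted p = 9.52e-05 in edgeR and adjusted p = 0.639 with an estimated correlation. Igkc fell by 1.82 (SE 0.16) and Jchain, which joins antibody units, fell by 2.68 (SE 0.41), while Mzb1 and Prdm1 did not pass (adjusted p = 0.611 and 0.716 in edgeR).

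Genes of glycolysis and of DNA replication fell as well. Of 19 glycolysis genes 12 fell and Aldoc rose by 0.57 (SE 0.14), with camera adjusted p = 0.00117 in edgeR and adjusted p = 0.703 with an estimated correlation. Slc16a3, a lactate exporter, fell by 0.86 (SE 0.13) and Ldha fell by 0.66 (SE 0.12). Of 23 S phase genes 13 fell, among them Rrm2 and Mcm6, and Ccne1 rose by 0.66 (SE 0.16), with camera adjusted p = 0.00089 in edgeR and adjusted p = 0.639 with an estimated correlation. Of 17 chemokine receptor and egress genes 6 rose and 4 fell (camera adjusted p = 0.647 in edgeR): Ccr7 rose by 1.58 (SE 0.13), while Ccr1 fell by 2.31 (SE 0.25), Cxcr4 fell by 0.83 (SE 0.17) and Ccr2 fell by 0.85 (SE 0.15). Cx3cr1, which overlaps Gm33858 and is uncertain, was the other that fell.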
